A study of Mus musculus with 18 samples.

How the data were processed

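RNA was sequenced from the brains of outbred CD-1 mice carrying 0, 1 or 2 copies of the Pten m3m4 knock-in allele. The 18 libraries fall into 6 groups of 3: microdissected cortex at 6 weeks and hemibrain at 2 weeks, each from wild-type, heterozygous and homozygous animals. Per the labels, frozen tissue was extracted with Trizol, treated with DNase, depleted of ribosomal RNA and made into stranded total RNA libraries, which were read as 100 base pair paired ends. The libraries were placed 3 to a lane, grouped in biological triplicates, and the lanes are not listed, so lane and genotype group may coincide and no lane term could be fitted. Age and tissue differ together, so no difference between the 6-week and 2-week results can be given to one of them.

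The authors deposited 1 table of all genes and libraries with estimated counts of fragments per gene (expected counts, before any scaling), and with FPKM (fragments per kilobase of transcript, relative to the library's total) after the authors' scaling. The submitters' processing notes name TopHat, Bowtie, Cufflinks and Cuffdiff and the mouse build mm10, without versions, settings, roles or the gene annotation. The counts are estimates because fragments shared between genes are divided among them, so paralogs and overlapping genes can borrow from each other. The scaled fragments in the table equal the unscaled ones divided by 1 factor per library. The table numbers the replicates from 0 to 2, and these were read as samples 1 to 3 of the titles. That reading moves no library between groups.

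Of the 23356 genes, 12 were left out because the table gives them a status other than OK in at least 1 library. They include Malat1 and Celf2, which the table marks as too deep to resolve. Library totals ran from 23476385 to 33832429 fragments. At that depth the spread between animals exceeds counting error for all but low transcripts: the common biological coefficient of variation was 11.9% in cortex and 14.4% in hemibrain. Pairs of replicates differed by far more than counting error, so no library was a copy of another. Fragments carry no molecular identifiers. Gene positions came from the GENCODE M21 and RefSeq annotations of the same build, matched by symbol or synonym for 99.33% of genes.

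The plan fixed before the data were examined was to test log2(FPKM + 1) with limma, and to use edgeR on rounded fragment counts in its place if the table held counts. It did, so each age was fitted with edgeR 4.0.16 in R 4.3.3: filterByExpr on the 3 groups, TMM scaling, glmQLFit and glmQLFTest with 1 mean per genotype and no replicate block. Between heterozygous and homozygous hemibrain the residuals of the libraries with the same number correlated at 0.54, 0.31 and 0.26, so the fit with the replicate number as a block is given beside that contrast. The pairing comes from this check and not from the labels. Heterozygous replicate 2 with homozygous replicate 3 reached 0.29 and the reverse 0.25, close to the 0.31 and 0.26 of the same numbers. Replicate 1 of either group correlated at -0.41 to -0.35 with replicates 2 and 3 of the other. Both replicate 1 libraries stood apart from the other hemibrain libraries, so these values do not show a pairing by number. In the other contrasts at least 1 such pair lay under 0.1. Genes with a Benjamini-Hochberg adjusted p under 0.05, two-sided, were called. The design filter of a mean FPKM of at least 1 became an alternative. The 3 genotypes of an age shared 1 estimate of the spread. Differences between ages came from 1 fit of all 18 libraries with 6 group means. Fold changes use a prior count of 0.125. CPM are counts scaled to the TMM-adjusted library size as edgeR reports them, given as mean ± SD, and log2 changes are given ± their standard error from the fit. For Pten an exact permutation test of the CPM was added, which with 3 against 3 cannot go below 0.1.

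Gene lists for brain cell types, brain regions and pathways, 40 in all, were also fixed before the data were examined, and 39 held tested genes. The mitochondrially encoded transcripts were missing from the table. Each list was tested with camera in limma 3.58.1 on log2 CPM at a preset correlation of 0.01, again with the correlation estimated from the samples, and with fry. Adjusted p values of lists are Benjamini-Hochberg values over the 39 lists. Camera asks whether a list moved against all other genes. Fry asks whether its members moved, on balance, in 1 direction. The called members of each list were also counted with p adjusted over the list alone.

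Genes were named by a rule fixed with the lists. Pten is always given. For each contrast the rule takes called genes whose groups do not overlap, with a mean FPKM of at least 1 in the higher group and a symbol that is not a short RNA and not a clone or predicted gene name of the form Gm plus digits, Rik, LOC, or AK or BC plus digits. Of these it takes the 12 highest and 12 lowest log2 changes for homozygous against wild-type, 8 and 8 for the other genotype contrasts, and 5 and 5 for differences between ages. Up to 4 members with the smallest adjusted p come from each list described.

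The methods were tested on simulated data of the same size and spread, with 50 genes changed at each fold. For homozygous against wild-type cortex, 6% of genes changed 1.25-fold were found, 42% at 1.5-fold, 82% at 2-fold and 98% at 4-fold. For the hemibrain these shares were 8%, 54%, 76% and 94%. For the other genotype contrasts 38% to 58% were found at 1.5-fold, and 28% for the differences between ages. Wrong calls numbered 3 to 12 per comparison. A list moved 1.5-fold was found by camera and by fry, with 1 wrong list by fry. Each gene was drawn on its own, while real members of a list move together. The count of wrong lists therefore does not test camera at the preset correlation on real data.

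The alternatives were limma on log2(FPKM + 1) with pseudocounts of 0.5 and 0.1, quantile or median-of-ratios scaling and sample weights, edgeR with DESeq2 size factors, DESeq2 1.42.0, other filters on low values, robust moderation, short RNA genes left out, a replicate block, a fold threshold, a fit of only the groups compared, a fit of all 18 libraries, and leaving out each library in turn. Alternatives added after the data were seen left out 2 hemibrain libraries that stood apart, removed each library's trend on transcript GC content and length, or added the myelin list score as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.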

Results

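RNA from mouse brain was measured in 18 libraries, 3 from each of 6 groups: wild-type, heterozygous and homozygous cortex at 6 weeks, and wild-type, heterozygous and homozygous hemibrain at 2 weeks. The animals were outbred CD-1 mice with a knock-in of the m3m4 allele of Pten, the lipid phosphatase that opposes PI3K signalling. The design text states that both mutant genotypes are to be compared with wild-type littermates at each age. Total fragments per library were 25210915, 25444212 and 23738834 in wild-type cortex, 24915152, 25349207 and 23980284 in heterozygous cortex and 24985714, 29283861 and 24706109 in homozygous cortex. In hemibrain they were 25752912, 29367731 and 28447835 in wild-type, 33832429, 27560757 and 23476385 in heterozygous and 32500870, 31714282 and 24108288 in homozygous libraries. The ribosomal precursor Rn45s took 1.83% of fragments in homozygous cortex replicate 2 and 0.808% in wild-type hemibrain replicate 2, against 0.141% to 0.248% in the other 16 libraries.

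The Pten transcript differed little between the genotypes, although each of the 6 mutant cortex libraries lay below the 3 wild-type ones, and each of the 3 homozygous hemibrain libraries below the 3 wild-type ones there. The gene lies on chromosome 19, from 32757497 to 32826160 on the plus strand of build mm10. Wild-type cortex held 476.9, 474.2 and 467.5 CPM in its 3 libraries, heterozygous cortex 433.6, 455.0 and 455.4, and homozygous cortex 452.5, 449.6 and 455.8. Wild-type hemibrain held 392.0, 393.5 and 391.6 CPM, heterozygous hemibrain 404.7, 386.1 and 401.5, and homozygous hemibrain 373.8, 383.9 and 389.3. In cortex the log2 change from wild-type was -0.06 ± 0.039 in homozygotes (exact permutation p = 0.1, the smallest possible) and -0.08 ± 0.039 in heterozygotes (exact permutation p = 0.1). In hemibrain it was -0.04 ± 0.047 in homozygotes (exact permutation p = 0.1) and 0.02 ± 0.047 in heterozygotes (exact permutation p = 0.4). No Pten contrast was called by edgeR, with adjusted p from 0.323 to 0.970 over the 6 contrasts. An interval of 2 standard errors around the homozygous change in cortex ran from -0.142 to 0.0157, and in hemibrain from -0.131 to 0.0564. A drop in transcript beyond these bounds lay outside the interval, and smaller changes were not detectable at this depth and number of animals.

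**Figure D1:**
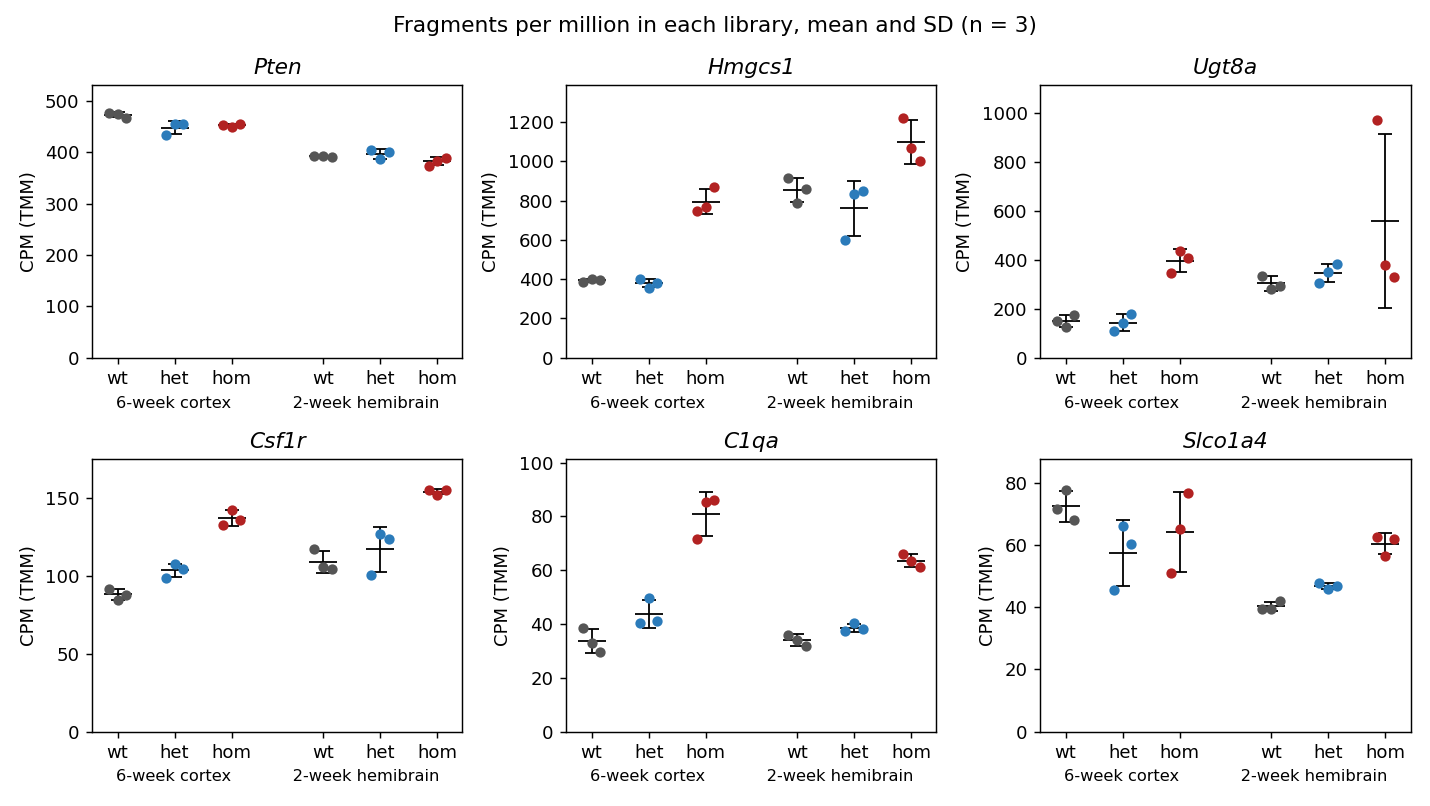
TMM-scaled counts (CPM, linear axes from 0) of 6 genes in each of the 18 libraries. Points are libraries, the horizontal mark is the group mean and the bar is 1 SD (n = 3). Pten stays near 1 level per tissue, while Hmgcs1, Ugt8a, Csf1r and C1qa sit higher in all 3 homozygous cortex libraries than in the 3 wild-type ones. The wide bar for Ugt8a in homozygous hemibrain comes from replicate 1.

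Cortex of homozygotes at 6 weeks held more transcript for making cholesterol than wild-type cortex. Hmgcs1 (chromosome 13, 119690351 to 119708260), which makes HMG-CoA for the sterol pathway, stood at 795 ± 64.3 CPM against 394 ± 8.49 (n = 3 each; log2 change 1.01 ± 0.066, adjusted p = 0.000434 by edgeR). Dhcr24, which reduces desmosterol to cholesterol, rose by 0.81 ± 0.054 (adjusted p = 0.000434), the sterol oxidase Sc4mol by 0.74 ± 0.056 (adjusted p = 0.000681) and the receptor gene Ldlr by 1.06 ± 0.083 (adjusted p = 0.00084). Of the 24 cholesterol synthesis genes, 22 rose, 0 fell and 2 did not pass. Adjusted over the list alone, 23 rose. The median log2 change was 0.63, and camera gave the list an adjusted p of 1.32e-48, or 0.00159 with an estimated correlation. The 4 named members stayed called in each of the 6 fits that left out 1 library. The myelin list, a measure of white matter, was also higher in these pieces, and with its score as a covariate, added after the data were seen, the cholesterol median was 0.63 with 3 genes called.

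Microglial genes were higher as well. Csf1r (chromosome 18, 61105572 to 61131139), the receptor microglia need to survive, stood at 137 ± 4.99 CPM against 88.2 ± 3.32 (log2 change 0.64 ± 0.053, adjusted p = 0.00084). C1qa (chromosome 4, 136895916 to 136898844), a chain of the first complement component, stood at 81.0 ± 8.18 against 33.8 ± 4.38 CPM (1.26 ± 0.12, adjusted p = 0.001). Olfml3 rose by 0.95 ± 0.078 and the signalling adaptor Tyrobp by 1.08 ± 0.11. Of 24 microglia genes, 16 rose and 0 fell, and 20 rose when adjusted over the list alone (median 0.69, camera adjusted p = 1.11e-30, and 0.0312 with an estimated correlation). With the myelin covariate the median was 0.47 and 0 microglia genes were called by edgeR, where the whole fit had 25 calls. In the complement list, which holds several of the same genes, 7 of 18 rose, also 7 over the list alone, C1qc by 1.26 ± 0.15 and Itgam by 1.00 ± 0.11 (median 0.87, adjusted p = 6.62e-08, and 0.125 with an estimated correlation). Of 15 genes of activated microglia 4 rose, 5 over the list alone, among them the lysosomal protease genes Ctsd, by 0.56 ± 0.071, and Ctsb, by 0.23 ± 0.052 (median 0.27, adjusted p = 0.00225, and 0.166 with an estimated correlation). The antigen presentation list had 1 called gene of 17, B2m, which rose by 0.37 ± 0.09, with 7 higher and 1 lower over the list alone (median 0.54, adjusted p = 0.00493, and 0.125 with an estimated correlation). The interferon list had 0 called genes of 22 by edgeR (median 0.40, adjusted p = 0.00493, and 0.391 with an estimated correlation). Ctsb and B2m each kept their call in 3 of the 6 fits without 1 library. Ctsb lost it without wild-type replicate 2 or 3 or homozygous replicate 2 (adjusted p = 0.0634 to 0.106) and B2m without any 1 of the wild-type libraries (0.0598 to 0.111).

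Genes of the oligodendrocyte lineage rose. Ugt8a (chromosome 3, 125865272 to 125938682), the enzyme that makes the main myelin galactolipid, stood at 397 ± 47.3 CPM against 150 ± 25 (log2 change 1.40 ± 0.18, adjusted p = 0.00318). Plp1, the chief protein of central myelin, stood at 4493 ± 627 against 1858 ± 278 CPM (1.27 ± 0.22, adjusted p = 0.0102). Fa2h rose by 1.31 ± 0.17 and Mag by 1.09 ± 0.17. Of 25 myelin genes 16 rose and 0 fell, and 22 rose over the list alone, with a median of 0.89 (adjusted p = 1.78e-21, and 0.167 with an estimated correlation). Of 15 precursor genes 7 rose and 0 fell, 10 over the list alone, among them Pdgfra by 0.50 ± 0.059, Olig1 by 0.79 ± 0.098, Olig2 by 0.79 ± 0.1 and Enpp6 by 1.24 ± 0.18 (median 0.55, adjusted p = 1.12e-10, and 0.00933 with an estimated correlation). The mean log2 CPM of the myelin list was 7.02 to 7.33 in the 3 homozygous libraries and 5.79 to 6.59 in the other 6 cortex libraries.

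Vessel genes rose too. The tight junction gene Cldn5 rose by 0.96 ± 0.091, the endothelial genes Vwf by 1.23 ± 0.14, Tie1 by 0.64 ± 0.089 and Pecam1 by 0.56 ± 0.08. Of 20 endothelial genes 9 rose and 0 fell, 14 over the list alone (median 0.42, adjusted p = 1.4e-10, and 0.00854 with an estimated correlation). Of 14 mural cell genes 7 rose and 0 fell, 8 over the list alone, with Rgs5 up by 0.96 ± 0.079 and Abcc9 by 0.85 ± 0.11 (median 0.61, adjusted p = 1.4e-10, and 0.0276 with an estimated correlation). With the myelin covariate the endothelial median was 0.56 with 3 genes called and the mural median 0.78 with 0 called. In astrocytes 7 of 20 genes rose, 12 over the list alone, among them the water channel gene Aqp4 by 0.86 ± 0.14 and Aldh1l1 by 0.47 ± 0.085 (median 0.26, adjusted p = 2.89e-05, and 0.236 with an estimated correlation). None of 14 reactive astrocyte genes was called by edgeR (median 0.37, adjusted p = 0.0397, and 0.58 with an estimated correlation).

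Genes of the lists for neurons, synapses, ion channels and autism risk moved in both directions, and these lists can hold genes that other cells express. Of 41 autism risk genes 9 fell and 0 rose, 12 lower over the list alone: Tsc1, a brake on mTOR signalling, by -0.31 ± 0.051, the neurexin relative Cntnap2 by -0.34 ± 0.057, the sodium channel gene Scn2a1 by -0.33 ± 0.064 and the histone methyltransferase gene Ash1l by -0.25 ± 0.051 (median -0.14, adjusted p = 4.32e-06, and 0.166 with an estimated correlation). Of 29 postsynaptic genes 4 fell and 1 rose, 4 and 2 over the list alone. The glutamate receptor genes Grik2 and Gria2 fell, by -0.53 ± 0.07 and -0.38 ± 0.087, and Grin2c rose by 0.43 ± 0.062 (median -0.11, adjusted p = 0.0143, and 0.517 with an estimated correlation). The neurofilament genes Nefl, Nefm and Nefh rose by 0.62 ± 0.08, 0.89 ± 0.14 and 0.79 ± 0.13 among 4 higher and 1 lower of 20 pan-neuronal genes, a list with an adjusted p of 0.0507. Of 22 potassium and sodium channel genes 3 rose and 3 fell, Kcnj10 up by 0.51 ± 0.1 and Scn3a down with a log2 change of -0.62 ± 0.093 (list adjusted p = 0.243). The glutamatergic list had 2 higher and 2 lower of 24 (adjusted p = 0.086), with Slc17a7 up by 0.31 ± 0.062 and Bcl11b at -0.67 ± 0.17. The GABAergic list had 2 higher, the neuropeptide genes Npy by 0.55 ± 0.079 and Cck by 0.45 ± 0.083, and 1 lower of 23 (adjusted p = 0.417). Synaptic vesicle genes had 2 higher of 26 (adjusted p = 0.272), GABA receptor genes 0 of 15 (adjusted p = 0.243), and immediate early genes 0 of 23 (adjusted p = 0.559). Several of these calls ended when 1 library was left out. Ash1l, Gria2 and Kcnj10 were not called without any 1 of the wild-type libraries (adjusted p = 0.0546 to 0.0851), Slc17a7 and Cck without wild-type replicate 1 or 2 (0.0571 to 0.0695), Scn2a1 without wild-type replicate 1 or 3 (0.0614 and 0.0596), and Bcl11b without wild-type replicate 1 or 2 or homozygous replicate 1 or 3 (0.0732 to 0.117).

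Among pathway lists, the PI3K, Akt and mTOR list had 2 higher and 3 lower of 40 genes, 2 and 5 over the list alone (median -0.10, adjusted p = 0.0493, and 0.166 with an estimated correlation). Inpp5d, a phosphatase expressed in microglia, rose by 0.50 ± 0.064, Pik3r3 rose by 0.41 ± 0.082 and the growth factor receptor gene Igf1r fell by 0.36 ± 0.07. FoxO targets had 2 higher and 2 lower of 25, Ccnd1 up by 1.19 ± 0.2 and Txnip at -0.46 ± 0.081 (list adjusted p = 0.199). Oxidative phosphorylation had 7 higher and 0 lower of 30, 11 over the list alone, with Cox5a up by 0.27 ± 0.049 (median 0.13, adjusted p = 2.13e-05, and 0.393 with an estimated correlation). The clock list had 2 lower of 16, Rorc at -1.75 ± 0.33 and Nr1d2 at -0.40 ± 0.098 (median -0.30, adjusted p = 0.000474, and 0.166 with an estimated correlation). Heat shock and unfolded protein genes had 1 higher of 26, Sdf2l1, and 0 over the list alone (median 0.19, adjusted p = 0.00707, and 0.458 with an estimated correlation). The 28 cell cycle genes had 0 calls (median 0.37, adjusted p = 0.00975, and 0.517 with an estimated correlation), and ribosomal protein genes had 1 lower of 29, Rpl14, and 0 over the list alone (median -0.10, adjusted p = 0.0493, and 0.242 with an estimated correlation). Lists without a call were neurogenesis with 4 higher of 21 (adjusted p = 0.816), meninges with 1 higher of 16 (0.978), choroid plexus with 0 of 18 (0.0644), blood with 1 higher of 12 (0.816), hippocampus with 2 higher of 15 (0.463), hindbrain, midbrain and thalamus with 1 higher of 15 (0.816), sex-linked transcripts with 0 of 9 (0.656), glucocorticoid response with 0 of 16 (0.645), histone genes with 1 higher of 18 (0.224) and long nuclear RNAs with 0 of 13 (0.134). In the meninges, immediate early, hindbrain, neurogenesis and sex-linked lists the median, the mean and the test did not share 1 sign. Sdf2l1 was called in none of the 6 fits that left out 1 library (adjusted p = 0.0586 to 0.114), and Nr1d2 only in the one without homozygous replicate 2 (0.0698 to 0.117 in the others). Rpl14 lost its call without any 1 of the wild-type libraries or homozygous replicate 2 (0.0737 to 0.132), Igf1r without any 1 of the wild-type libraries (0.0519 to 0.0695), Pik3r3 without wild-type replicate 1 or 2 (0.0676 and 0.0683), Txnip and Rorc without wild-type replicate 1 (0.0524 and 0.0544) and Cox5a without wild-type replicate 3 (0.0524).

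Markers of striatum differed between the cortex pieces. The mean log2 CPM of the striatum list was 5.01, 4.30 and 3.61 in the wild-type libraries, 2.87, 4.07 and 5.26 in the heterozygous ones and 2.48, 3.70 and 2.61 in the homozygous ones. None of its 16 genes was called in homozygotes (median -1.21, adjusted p = 7.42e-05, and 0.469 with an estimated correlation).

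The rule for named genes gave the largest changes. Those that rose were Meox1 (2.12 ± 0.34), Crlf1, Acaa1b, Snai3, the apelin receptor gene Aplnr (1.86 ± 0.27), the microglial gene Fcrls (1.85 ± 0.25), Ace2 (1.73 ± 0.17), Ctla2a, Cldn14 (1.43 ± 0.39), the endothelial gene Cd93 (1.43 ± 0.25), Slc45a3 (1.42 ± 0.17) and Ugt8a. Those that fell were Baiap3 (-2.20 ± 0.4), the kappa opioid receptor gene Oprk1 (-1.73 ± 0.47), AW551984, Adam33 (-1.47 ± 0.27), Abi3bp, Klhl1 (-1.29 ± 0.14), Cntnap3, Lrrc23, Xirp2 (-0.998 ± 0.099), Abca8a, Masp2 and Iqub (-0.96 ± 0.17). Most were transcripts of low level: Meox1 stood at 2.12 ± 0.522 against 0.485 ± 0.224 CPM and Baiap3 at 1.48 ± 0.286 against 6.82 ± 4.11. Of these 24 genes 12 stayed called in each of the 6 fits without 1 library, namely Meox1, Aplnr, Fcrls, Ace2, Cd93, Slc45a3, Ugt8a, Adam33, Baiap3, Klhl1, Iqub and Xirp2. Without wild-type replicate 2, which ended the most calls, 12 of the 24 were kept, and Oprk1 was called in none of the 6 fits.

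In all, edgeR called 914 genes higher and 664 lower of 15370 tested in homozygous against wild-type cortex. Of these, 471 changed at least 1.5-fold and 136 at least 2-fold. At an unadjusted p under 0.05 there were 4442 genes, and the 2 groups did not overlap in 33.9% of tested genes, where chance gives 10%. The count fell to 448 without wild-type replicate 1, 472 without replicate 2 and 584 without replicate 3. With the myelin list score as a covariate, an alternative chosen after the data were seen, 25 genes were called, 17 of them among the 1578.

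**Figure D2:**
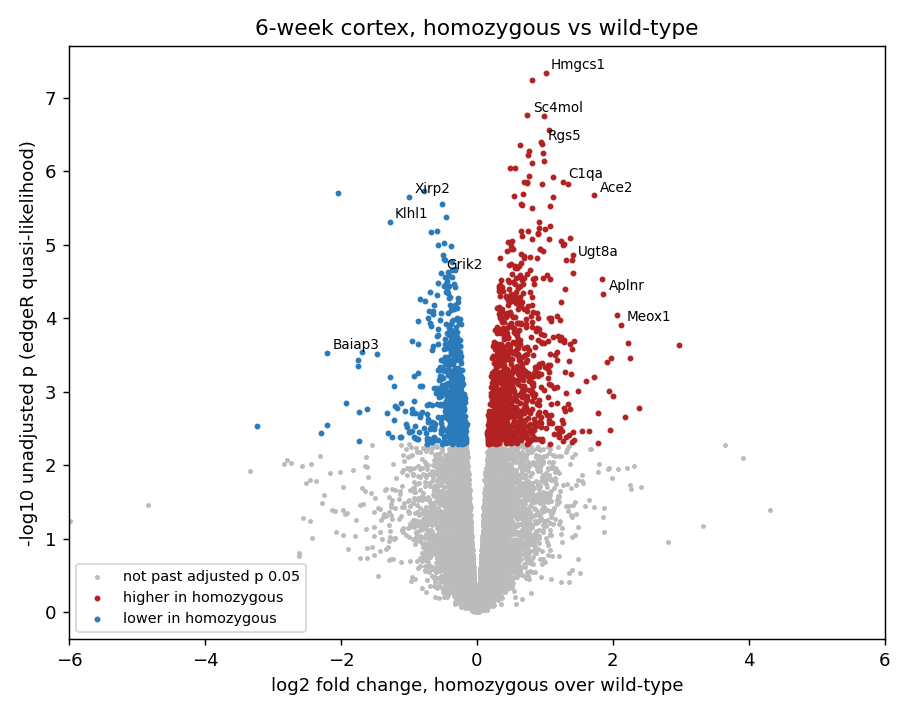
Each point is 1 of the 15370 genes tested in cortex at 6 weeks: log2 fold change of homozygous over wild-type against -log10 of the unadjusted p from edgeR. Red points (914) are higher and blue points (664) lower at an adjusted p under 0.05, and 2 genes lie at or beyond the ends of the horizontal axis. Hmgcs1 has the smallest p.

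In heterozygous cortex at 6 weeks no gene passed the test against wild-type. Hmgcs1 stood at 379 ± 21.2 CPM against 394 ± 8.49, Ugt8a at 144 ± 33.8 against 150 ± 25 and Csf1r at 104 ± 4.46 against 88.2 ± 3.32 (n = 3 each), and none of these was called (adjusted p = 0.880, 0.962 and 0.729 by edgeR). The 24 microglia genes had 0 calls by edgeR, 2 higher over the list alone and a median log2 change of 0.16 (camera adjusted p = 1.86e-05, and 0.512 with an estimated correlation). Synaptic vesicle genes had 0 calls, 1 higher over the list alone and a median of 0.07, with Bsn at 0.38 ± 0.088 (camera adjusted p = 1.4e-05, and 0.512 with an estimated correlation). Camera called 13 lists higher: these 2 and the astrocyte, endothelium, mural cell, meninges, pan-neuronal, glutamatergic, immediate early, autism risk, postsynaptic, channel and heat shock lists. It called 2 lower, choroid plexus (median -1.03) and cell cycle (median -0.15). No list was called with an estimated correlation, where the adjusted p of these 15 ran from 0.512 to 0.713. Of 15370 genes edgeR called 0, with 1023 at an unadjusted p under 0.05 and a smallest adjusted p of 0.729, for Vgf. The groups did not overlap in 18.1% of genes, where chance gives 10%. DESeq2 called 17 and limma on FPKM 0. In simulated data for this contrast 82% of genes changed 2-fold were called, 58% of those changed 1.5-fold and 6% of those changed 1.25-fold.

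Homozygous cortex also held more cholesterol, precursor and endothelial transcript than heterozygous cortex. Of 24 cholesterol genes 20 rose and 0 fell, 23 over the list alone, with Hmgcs1 up by 1.07 ± 0.066 (camera adjusted p = 2.29e-48, and 0.00185 with an estimated correlation). The precursor list had 8 higher of 15, 10 over the list alone (adjusted p = 0.0136 with an estimated correlation), and the endothelium list 9 higher of 20, also 9 over the list alone (adjusted p = 0.0155 with an estimated correlation). Myelin had 18 higher of 25, 22 over the list alone (adjusted p = 0.14 with an estimated correlation), and microglia 14 higher of 24, 17 over the list alone (adjusted p = 0.061 with an estimated correlation). Of 41 autism risk genes 17 fell and 0 rose, 21 over the list alone, among them Pogz by -0.45 ± 0.065 and Auts2 by -0.51 ± 0.075 (median -0.26, camera adjusted p = 6.53e-12, and 0.061 with an estimated correlation). The presynaptic scaffold genes Bsn and Pclo fell, by -0.44 ± 0.088 and -0.38 ± 0.076, among 3 lower of 26 vesicle genes (list adjusted p = 0.213). Both lost their call without homozygous replicate 2 or heterozygous replicate 2, and Pclo also without heterozygous replicate 1 (adjusted p = 0.0514 to 0.0821). Genes named by the rule that rose were Acaa1b (2.26 ± 0.37), Meox1 (2.15 ± 0.34), Cldn14, Depdc1b (1.67 ± 0.25), Ugt8a (1.47 ± 0.18), the protease gene Klk6, Ctla2a and Ppp1r14a (1.39 ± 0.24). Those that fell were Baiap3 (-2.09 ± 0.4), the collagen gene Col1a1 (-1.88 ± 0.5), the nuclear receptor gene Nr4a2 (-1.32 ± 0.23), Klhl1 (-1.14 ± 0.14), Traip, Phf21b, Igflr1 and Ogn (-0.91 ± 0.19). Of these 16, Acaa1b, Depdc1b, Klhl1, Ppp1r14a and Ugt8a stayed called in each of the 6 fits without 1 library.

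Camera called 21 lists between homozygous and heterozygous cortex. Higher were the astrocyte, activated microglia, interferon, antigen presentation, complement, mural cell, cell cycle and oxidative phosphorylation lists besides those already given. Lower were the autism risk, glutamatergic, striatum, immediate early, PI3K, postsynaptic, channel and clock lists. The 18 calls not kept with an estimated correlation had an adjusted p of 0.061 to 0.564 there. In all, edgeR called 761 genes higher and 700 lower of 15370, with 4249 at an unadjusted p under 0.05, and the groups did not overlap in 30.3% of genes, where chance gives 10%. The count fell to 225 without heterozygous replicate 2, 636 without heterozygous replicate 1, 869 without heterozygous replicate 3 and 957 without homozygous replicate 2, and to 275 in a fit of these 2 groups alone.

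In 2-week hemibrain, 3 genes rose in homozygotes and 0 fell. C1qa stood at 63.6 ± 2.31 CPM against 33.99 ± 2.1 in wild-type (log2 change 0.90 ± 0.065, adjusted p = 0.00353 by edgeR), and its partner chain C1qb at 24.2 ± 1.69 against 13.2 ± 1.28 (0.88 ± 0.094, adjusted p = 0.0315). Slco1a4, a transporter gene of brain endothelium, stood at 60.3 ± 3.36 against 40.3 ± 1.46 CPM (0.58 ± 0.061, adjusted p = 0.0315). In 6-week cortex it was not higher, at 50.84, 64.97 and 76.61 CPM in homozygotes against 71.63, 77.75 and 67.92 in wild-type. C1qa lost its call without wild-type replicate 2 (adjusted p = 0.0626). C1qb lost it without wild-type replicate 2 or 3 or homozygous replicate 2 or 3 (0.251, 0.265, 0.212 and 0.139), and Slco1a4 in each such fit except the one without homozygous replicate 1 (adjusted p = 0.0562 to 0.251). In 1 fit of all 18 libraries C1qa alone of the 3 was called. A fit of only the groups compared called none of them, and the replicate block did not call Slco1a4. Of 24 microglia genes 2 rose, and 15 over the list alone, with a median of 0.50 (camera adjusted p = 3.12e-44, and 0.0253 with an estimated correlation). The complement list had 2 higher of 18, 6 over the list alone (median 0.62, adjusted p = 0.0253 with an estimated correlation), and activated microglia 0 of 15, 4 over the list alone (median 0.29, adjusted p = 0.0274 with an estimated correlation). The estimated correlation kept none of these 3 lists without 2 set-apart libraries, described next (adjusted p = 0.103 for microglia, 0.156 for complement and 0.184 for activated microglia), and their medians were 0.49, 0.346 and 0.22. Cholesterol genes had 0 calls of 24, 7 higher over the list alone and a median of 0.32 (camera adjusted p = 4.12e-13, and 0.288 with an estimated correlation), and endothelial genes 1 of 20, 4 over the list alone (median 0.16, adjusted p = 0.167 with an estimated correlation).

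In hemibrain 1 heterozygous and 1 homozygous library stood apart. Homozygous replicate 1 and heterozygous replicate 1 had 623 and 407 CPM of Xist, the RNA of the inactive X chromosome, where the other 7 hemibrain libraries had at most 1.07 and the 9 cortex libraries at most 1.97. Their summed Y-linked transcripts were 0.346 and 0.182 CPM, against at least 321 in the other 7. On the first principal component of hemibrain, with 41.1% of the variance, these libraries stood at 47.2 and 36.9 and the others from -14.8 to -8.28. Homozygous replicate 1 also held 8230 CPM of Mbp, the myelin basic protein gene, where the other 8 held 2130 to 3220. The myelin list moved with it: its median change in homozygotes was 0.98 with 0 of 25 genes called (adjusted p = 0.406 with an estimated correlation), and 0.21 without both set-apart libraries.

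Without these 2 libraries, left out after the data were seen, 20 genes rose and 5 fell in homozygous hemibrain. C1qa rose by 0.88 ± 0.059 (adjusted p = 0.00117 by edgeR), Csf1r by 0.50 ± 0.052 (0.00966), the lysosomal enzyme gene Hexb by 0.48 ± 0.046 (0.0093), the macrophage gene Emr1 by 0.69 ± 0.071 (0.00966) and the chemokine receptor gene Cx3cr1 by 0.45 ± 0.052 (0.0112). Slco1a4 rose by 0.56 ± 0.056 (0.00966), Ace2 by 1.22 ± 0.18 (0.0367) and Insig1, a sterol sensor gene, by 0.35 ± 0.043 (0.0156). Of 24 microglia genes 9 rose (median 0.49, adjusted p = 0.103 with an estimated correlation). In this fit homozygotes have 2 libraries and heterozygotes 2.

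With all libraries, edgeR called 3 of 15772 genes in homozygous hemibrain, with 1348 at an unadjusted p under 0.05, and the groups did not overlap in 16.6% of genes, where chance gives 10%. DESeq2 called 59 and limma on FPKM 3. Camera called 17 lists. Besides those given, the precursor, astrocyte, reactive astrocyte, interferon, antigen presentation and mural cell lists were higher, and the glutamatergic, striatum, immediate early, postsynaptic and neurogenesis lists were lower. The 14 calls that were not kept with an estimated correlation had an adjusted p of 0.167 to 0.745 there. The antigen presentation and immediate early lists were not called without the 2 set-apart libraries (camera adjusted p = 0.0573 and 0.4).

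Heterozygous hemibrain had no called gene at 2 weeks. Fibcd1 came nearest, at 16.6 ± 0.0635 CPM against 28.6 ± 2.41 (log2 change -0.78 ± 0.081, adjusted p = 0.0709 by edgeR). Of 15772 genes edgeR called 0, with 370 at an unadjusted p under 0.05, DESeq2 3 and limma on FPKM 0. The 370 are fewer than that threshold gives on average where no gene changes. The groups did not overlap in 13.6% of genes, where chance gives 10%. Camera called the myelin, complement, meninges, immediate early, channel, clock and glucocorticoid lists higher and the precursor, cell cycle, neurogenesis and cholesterol lists lower, and each of these 11 had an adjusted p of 0.876 with an estimated correlation. The precursor, channel, cell cycle, cholesterol, clock and glucocorticoid lists lost their call when the 2 set-apart libraries were left out (camera adjusted p = 0.108 to 0.899), and there the precursor and cell cycle lists pointed up and the channel list down.

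Between homozygous and heterozygous hemibrain 1 gene was called, C1qa, at 63.6 ± 2.31 against 38.6 ± 1.51 CPM (0.72 ± 0.07, adjusted p = 0.0238). It lost its call without heterozygous replicate 1, 2 or 3 (adjusted p = 0.161, 0.146 and 0.201) and without homozygous replicate 2 or 3 (0.203 and 0.123), and with the replicate number as a block (0.72 ± 0.066, adjusted p = 0.106), where edgeR called 0 genes with 1467 at an unadjusted p under 0.05. A fit of only the groups compared did not call C1qa either. DESeq2 called 93 genes, limma on FPKM 1, and 1441 had an unadjusted p under 0.05 in the main fit. The groups did not overlap in 14% of genes, where chance gives 10%. Of 24 microglia genes 1 rose, and 17 over the list alone (median 0.43, adjusted p = 0.0414 with an estimated correlation, 0.0818 with the block and 0.314 without the 2 set-apart libraries). Camera called 19 lists, and the other 18 had an adjusted p of 0.0681 to 0.632 with an estimated correlation. Higher were myelin, precursor, astrocyte, reactive astrocyte, activated microglia, interferon, antigen presentation, complement, endothelium, mural cell, hindbrain, cholesterol and oxidative phosphorylation, and lower were meninges, glutamatergic, immediate early, postsynaptic and clock. Myelin and hindbrain rested on the 2 set-apart libraries: without them myelin (median -0.0204, camera adjusted p = 0.332) and hindbrain (median -0.0289, 0.923) pointed down and were not called, and the astrocyte, antigen presentation, glutamatergic, postsynaptic and clock lists kept their direction without a call (adjusted p = 0.0782 to 0.463).

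**Figure D3:**
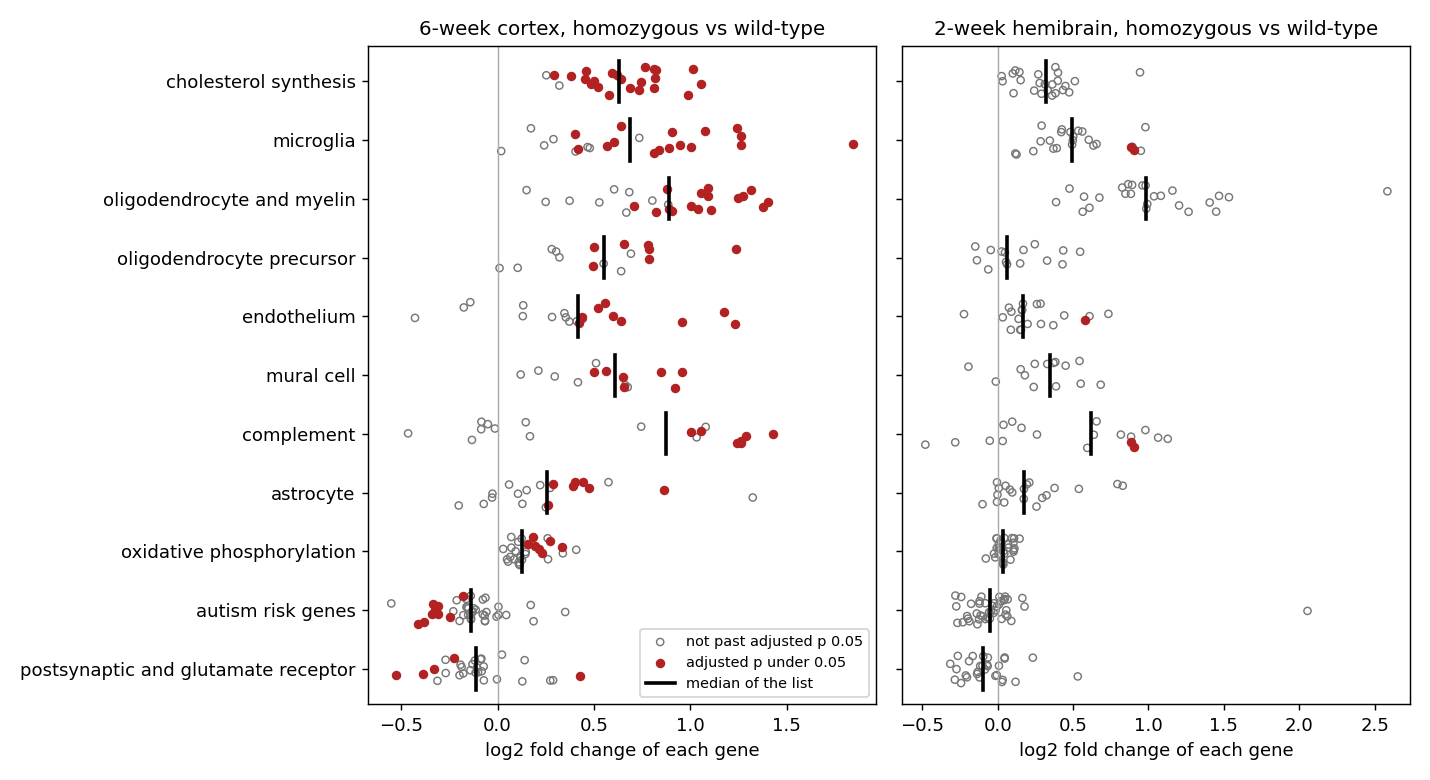
Log2 fold change of homozygous over wild-type for each gene of 11 lists, in cortex at 6 weeks and hemibrain at 2 weeks (separate horizontal scales). Filled red points passed an adjusted p of 0.05 over all genes, open points did not, and the black bar is the list's median. Cholesterol genes have a median of 0.63 in cortex and 0.32 in hemibrain, and microglia genes 0.69 and 0.50.

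**Figure D4:**
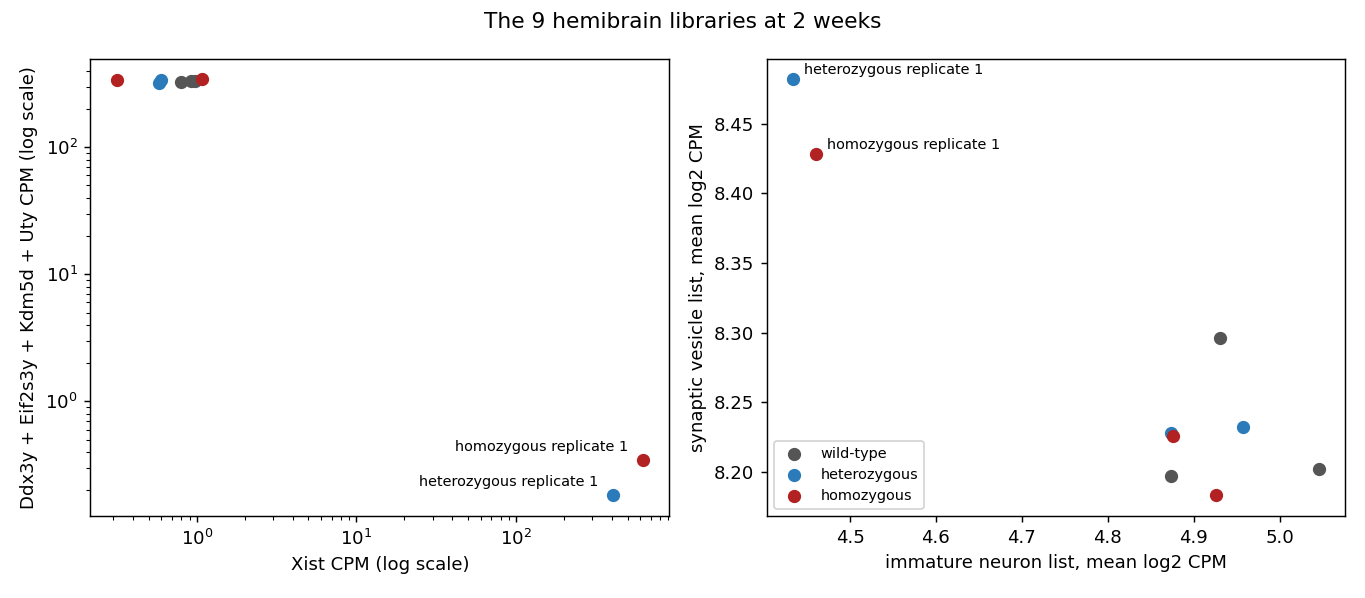
The 9 hemibrain libraries at 2 weeks, coloured by genotype. On the left the CPM of Xist is set against the summed CPM of 4 Y-linked genes (log scales), and on the right the mean log2 CPM of the immature neuron list against that of the synaptic vesicle list. Heterozygous replicate 1 and homozygous replicate 1 lie apart from the other 7 in both panels.

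Whether the genotype effects differed between the ages was tested directly. Of the genes called in homozygous cortex, 1571 were tested in hemibrain and 1289 of these, 82%, had the same sign there, while 3 genes in all were called in hemibrain. The share over all tested genes was not computed. Genes of a list move together, so the 1289 are not separate agreements. The difference between ages had 0 called genes of 15913 for homozygotes by edgeR, with 1582 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0805 for Lynx1, an inhibitor of nicotinic receptors (0.51 ± 0.074). DESeq2 called 48 and limma on FPKM 0. For heterozygotes 0 were called by edgeR, with 480 at an unadjusted p under 0.05, and 0 by DESeq2 and by limma on FPKM. The 480 are fewer than that threshold gives on average where no gene changes. Without the 2 set-apart hemibrain libraries 46 genes had a more positive and 10 a more negative homozygous change in cortex than in hemibrain. More positive were Hmgcs1 by 0.74 ± 0.096 (adjusted p = 0.0132), Dhcr24 by 0.60 ± 0.083 (0.0141), Ldlr by 0.67 ± 0.12 (0.0266), Cldn5 by 0.66 ± 0.11 (0.0245) and the calcium-sensing receptor gene Casr by 1.47 ± 0.16 (0.00398). Tissue and age differ together here.

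Heterozygous and homozygous changes were also compared across genes. Both are measured against the same wild-type libraries, which alone makes them correlate. Across 15370 genes in cortex Pearson's r was 0.401, and simulated data with shared controls and no genotype effect gave 0.498. In hemibrain r was 0.51 across 15772 genes against 0.495 in simulated data. Without the 2 set-apart libraries it was 0.261, against 0.395 simulated at those group sizes. The covariance of the changes was 0.0314 in cortex, where simulation gave 0.0249 ± 0.0014 (SD over 50 runs), and 0.0312 in hemibrain, where it gave 0.0268 ± 0.0011. The hemibrain covariance was 0.0118 without the 2 set-apart libraries, below the simulated 0.0147 ± 0.00088. With median-of-ratios scaling of FPKM it was 0.0139 in cortex and 0.0166 in hemibrain, on a scale that was not simulated. The simulation draws each gene on its own while real genes move together, so its SD understates the spread of the covariance. It also gives every library the spread pooled over the genotypes. Pairs of wild-type cortex libraries differed less than homozygous pairs did, so the simulated covariance may be too high. A change in homozygotes alone also lowers r. The comparison therefore does not decide whether the genotypes share an effect, and 0 genes were called in both genotypes at either age.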

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

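The tests of a lower share of neurons, of female and of older animals and of stage as the source of hindbrain transcript, and the fits without the 2 set-apart libraries, with a GC and length correction and with a myelin covariate were chosen after the results were seen.

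What drew attention in 19 cases was a difference between the ages in how a gene list answered to genotype, tested by camera on the interaction term at the preset correlation. None of the 19 was kept with an estimated correlation, where the adjusted p was 0.413 to 0.588 for homozygotes and 0.974 for heterozygotes. For homozygotes, 12 of 39 lists differed. More positive in 6-week cortex than in 2-week hemibrain were cholesterol synthesis (adjusted p = 6.79e-11, median difference 0.30), oligodendrocyte precursor (3.71e-06, 0.38), cell cycle (0.00033, 0.50), oxidative phosphorylation (0.000946, 0.11), microglia (0.00301, 0.21), heat shock and unfolded protein (0.00447, 0.14), mural cell (0.00536, 0.28) and neurogenesis (0.0427, median 0.11 but mean -0.03). More negative in cortex were striatum (1.53e-06, -1.03), circadian clock (0.000127, -0.26), potassium and sodium channels (0.00281, -0.25) and autism risk genes (0.0034, -0.12). For heterozygotes, 7 of 39 lists differed. Myelin (0.000146, -0.51), glucocorticoid response (0.00272, -0.26) and choroid plexus (0.0116, -0.92) were more negative in cortex, and cholesterol synthesis (0.0195, 0.12), microglia (0.0283, 0.14), oligodendrocyte precursor (0.0365, 0.12) and neurogenesis (0.0365, median 0.19 but mean -0.0047) more positive. Tissue differs with age throughout, so the age itself was not tested.

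Glial, vascular and cholesterol genes rose together in homozygous cortex, which white matter cut with the cortex could cause. With the myelin score held constant the microglia median was 0.47, after 0.69 without it. The medians of the cholesterol, endothelium and mural lists were 0.63, 0.56 and 0.78 there. No microglia gene stayed called in that fit and 25 genes were called in all, 17 of them among the 1578. The score had an r of 0.939 with genotype over the 6 libraries. The median standard error of the 1578 genes went from 0.082 to 0.14 and of the microglia genes from 0.13 to 0.21. The median absolute log2 change of the 1578 went from 0.411 to 0.345. Other medians moved widely in that fit, striatum from -1.21 to -3.28 and meninges from -0.149 to 0.697. So the fit cannot separate white matter from genotype, and white matter stays open for the glial, vascular and cholesterol lists. A lower share of neurons with the other types unchanged would raise all their markers alike, but microglia rose beyond astrocytes by 0.393 on the log2 scale (exact permutation p = 0.0119 over 84 arrangements of the 3 homozygous and 6 other libraries), which argues against it as the whole cause. Endothelium rose beyond astrocytes by 0.117 (exact permutation p = 0.119), which a lower share of neurons could also give. Mural cell, precursor, cholesterol and myelin genes rose beyond astrocytes by 0.256, 0.274, 0.378 and 0.663 (exact permutation p = 0.0119, 0.0238, 0.0119 and 0.0357). A lower share of neurons would also lower neuronal markers. Their medians were 0.04 for the pan-neuronal, 0.05 for the synaptic vesicle, -0.15 for the glutamatergic and -0.06 for the GABAergic list, which does not settle it. GC content and transcript length are argued against too, since 45 of 48 called members of the microglia, myelin, endothelium and mural cell lists stayed called with that trend removed (median log2 change 0.905 before and 0.885 after), as did 21 of 22 cholesterol genes (0.664 and 0.648) and 6 of 7 precursor genes (0.778 and 0.66). That argument covers these lists only: over all genes 1252 were called with the trend removed, 1086 of them among the 1578. The striatum list also differed between the pieces, with a median of -1.21 in this contrast and scores that overlapped between genotypes. Lane may coincide with genotype, since the labels group the libraries of a lane in triplicates and list no lanes. More cells of these types, more transcript per cell, and a shift in dissection between genotypes stay open, so a biological reading is a hypothesis only.

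The other pattern is the pair of hemibrain libraries that stood apart, heterozygous and homozygous replicate 1. Their lowest Xist level was 382 times the highest of the other 7 libraries and their Y-linked level was 0.108% of the lowest, which is consistent with female animals among male ones. Their immature neuron score lay 0.413 below the lowest of the other 7 and their synaptic vesicle score 0.131 above the highest, which is consistent with older animals or a later stage, and sex and stage go together in these 2. For the heterozygous library the hindbrain score was -0.658 from the highest of the other 7 and inside their range, which was to count against tissue from cerebellum or hindbrain. That bound was too weak for a small share, since the cerebellar genes Gabra6 and Pcp2 stood at 8.98 and 1.58 CPM, against at most 1.42 and 0.346 in the other 7, so such tissue stays open there. The homozygous library held 55.8 CPM of Gabra6, 64.7 of Cbln1, 25.1 of Slc6a5 and 2.61 of Hoxb5. The other 7 held at most 1.42, 26.6, 0.893 and 0.157. Its hindbrain score lay 1.4 above that of the heterozygous library, more than the 0.943 range of the other 7. By the immature neuron scores (4.461 and 4.434) and the synaptic vesicle scores (8.428 and 8.482) both look about equally late. This argues against stage, as these scores measure it, as the source. Single genes differed more between the homozygous and heterozygous library: Mbp at 8230 and 3220 CPM, Pvalb at 106 and 54.9, Sox11 at 32.5 and 40.8. A difference in stage that the scores miss therefore stays open. The hindbrain score of the homozygous library lay above the highest of the other 7 by 0.746. That was short of the width of their range, which had been set as the bound, so the score does not decide on tissue from cerebellum or hindbrain. The levels of Gabra6, Cbln1, Slc6a5 and Hoxb5 above, and Pcp2 at 9.61 CPM against at most 0.346, go with such tissue in this library.

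Regrouping the libraries tests whether a count could come from chance, but the 6 libraries of a contrast give 10 splits, too few for a share under 0.05. The real counts and the highest of the other splits were 1578 and 1 for homozygous against wild-type cortex (1 of 10 splits as large), 0 and 2 for heterozygous against wild-type cortex (10 of 10), 1461 and 8 for homozygous against heterozygous cortex (1 of 10), 3 and 0 for homozygous against wild-type hemibrain (1 of 10), 0 and 1 for heterozygous against wild-type hemibrain (10 of 10), and 1 and 3 for homozygous against heterozygous hemibrain (2 of 10). In that contrast the 3 other splits that part all 3 pairs of the same number gave 0 genes, and the split with 3 genes parts 1 pair. A pairing by number was not shown there, since replicates 2 and 3 correlated about as much across numbers. For the difference between ages 100 splits were drawn, with a highest other count of 281 for homozygotes and 1 for heterozygotes. Where the real count is 0 all splits reach it by construction (here 100 of 100), so these counts say nothing about chance. The split with 281 genes keeps the real groups in cortex and regroups the hemibrain libraries, so the cortex difference between the genotypes is part of it.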

How the results depend on the processing

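The fits without the set-apart libraries, with GC and length removed and with the myelin covariate were chosen after the data were seen. In each result below the cause was not tested, except that a fit of 2 groups, a left-out library and a fold threshold use fewer libraries or keep fewer genes by construction, and that with the myelin covariate the standard errors rose.

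For homozygous against wild-type cortex (1578 genes) the replicate block gave 1031, only the 2 groups 981, a log2 change of at least 0.5 gave 595 and the myelin covariate 25, while leaving out 1 library gave 448 to 1561. With GC and length removed 1252 were called there, 1086 of them among the 1578. For homozygous against heterozygous cortex (1461) the 2 groups alone gave 275, the fold threshold 480 and left-out libraries 225 to 1486. For heterozygous against wild-type cortex (0) DESeq2 gave 17, the 2 groups alone 2 and left-out libraries 0 to 1. For homozygous against wild-type hemibrain (3) sample weights gave 21, DESeq2 59, the 2 groups alone 0, all 18 libraries 9 (with 1 of the 3 kept, C1qa), both set-apart libraries left out 25 and each library left out 0 to 5. For heterozygous against wild-type hemibrain (0) sample weights and DESeq2 gave 3 each and left-out libraries 0. For homozygous against heterozygous hemibrain (1) sample weights gave 22, the FPKM filter at 1 gave 2, robust moderation 2, the replicate block 0, DESeq2 93, the 2 groups alone 0, both set-apart libraries left out 18, all 18 libraries 3 and each library left out 0 to 3. For the homozygous difference between ages (0) median-of-ratios scaling gave 1, sample weights 46, the FPKM filter at 5 gave 1, DESeq2 48, both set-apart libraries left out 56 and each library left out 0 to 11, the highest without 2-week homozygous replicate 1. For heterozygotes (0) every alternative run gave 0. The r between heterozygous and homozygous changes in hemibrain, 0.51, was 0.261 without the set-apart libraries, where simulated data without a genotype effect gave 0.395.

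List calls fell with an estimated correlation from 21 to 5 and from 15 to 0 in cortex against wild-type (homozygous, heterozygous), from 21 to 3 between the mutants, and in hemibrain from 17 to 3, 11 to 0 and 19 to 1. Fry kept 0 of the 15 in heterozygous cortex and called 3, 0 and 2 in hemibrain, and 16 and 18 for the homozygous cortex contrasts. With the myelin covariate Cldn14 changed sign, to a log2 change of -0.23 (adjusted p = 0.884). Other named genes kept their sign wherever they were called, but calls were lost in 385 of 3926 values of named genes and list members for homozygous against wild-type cortex (167 with 1 library left out, 34 on FPKM), 360 of 3575 for homozygous against heterozygous cortex (180 and 49), 16 of 1491 for homozygous against wild-type hemibrain (10 and 0) and 7 of 1685 for homozygous against heterozygous hemibrain (5 and 0). These totals also count values of genes that were not called, which have no call to lose. In hemibrain the called genes were 3 against wild-type and 1, C1qa, against heterozygotes, so the shares there understate how often calls ended. Against heterozygotes C1qa kept its call in 1 of the 6 fits without 1 library. Pten was called in no alternative, with log2 changes of -0.11 to 0.04 for homozygous cortex. Residuals of libraries with the same replicate number correlated at -0.1 to 0.21 in cortex and -0.15 to 0.54 in hemibrain, and above 0.1 in all 3 pairs only between heterozygous and homozygous hemibrain. There the block ended the call of C1qa and, with an estimated correlation, that of the microglia list (0.0818). Replicates 2 and 3 of those groups correlated about as much across numbers (0.29 and 0.25), so a pairing by number was not shown. In homozygous against wild-type hemibrain the block gave 3 genes without Slco1a4 (adjusted p = 0.0614). List tests were not repeated with single libraries left out. At this depth and with 3 animals per group, genes changed 1.25-fold were found in 6% of simulated cases for homozygous cortex, so changes of that size are mostly out of reach.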

Other observations

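The test of linked variants and the fits without the set-apart libraries were chosen after the results were seen, and so were the genes named here.

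Without the 2 set-apart hemibrain libraries 56 genes had homozygous changes that differed between cortex and hemibrain, and several of these act on lipids but belong to no list used here. No test asked whether such genes were more frequent among the 56 than among all genes. The fatty acid elongase genes Elovl5, Elovl7 and Elovl2 had more positive changes in cortex by 0.40 ± 0.061, 0.89 ± 0.14 and 0.58 ± 0.1 (log2, adjusted p = 0.0171, 0.0218 and 0.0319 by edgeR). So did Npc2, which carries sterols out of lysosomes (0.51 ± 0.09, adjusted p = 0.0309), Slc25a1, which exports citrate for lipid synthesis (0.56 ± 0.093, 0.0229), and Gal3st1, which makes the myelin lipid sulfatide (0.91 ± 0.15, 0.0245). Txnip, a redox and glucose uptake regulator, changed the other way (-1.05 ± 0.17, 0.0218), as did Rorc, a clock regulator (-2.50 ± 0.49, 0.0481). With all libraries none of these differences between ages was called, and in this fit 2 libraries represent homozygous hemibrain.

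Among the 25 genes called in homozygous against wild-type hemibrain without these libraries, Igfbp3 rose by 0.63 ± 0.069 (adjusted p = 0.00968), Ly6c1 by 0.56 ± 0.079 (0.0334), the pericyte channel gene Kcnj8 by 0.90 ± 0.13 (0.0334) and Gpnmb, a gene of lipid-laden phagocytes, by 1.85 ± 0.23 (0.0156). Myoc fell by 1.28 ± 0.16 (0.0156) and the splicing kinase gene Clk1 by 0.54 ± 0.07 (0.0232).

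In heterozygous hemibrain 5 of the 46 genes at an unadjusted p under 0.01 lay between 3639961 and 21292422 on chromosome 5, all 5 lower: Gatad1 (-0.22), Gtpbp10 (-0.81), Gm8773 (-2.51), the transporter gene Abcb1b (-2.14) and Ccdc146 (-0.83). Their adjusted p was 0.582 to 0.95, and their groups did not overlap. The 46 genes are fewer than an unadjusted p under 0.01 gives on average where no gene changes. Pten is on chromosome 19, so a variant linked to the knock-in would not sit here, but variants carried by single outbred animals might move neighbours together. In the 9 cortex libraries, a separate set, 4 of the 5 genes were tested, and the median Spearman rho of their 6 pairs was 0.575. Of 10000 draws of 4 genes from a random window of 20 Mb 79 had a median as high, which is consistent with linked variants. The pairs ran from -0.233, for Gtpbp10 and Ccdc146, to 0.8, for Gatad1 and Abcb1b (exact permutation p = 0.552 and 0.0138, adjusted 0.552 and 0.0622; Pearson's r -0.051 and 0.808, exact p = 0.895 and 0.00901, adjusted 0.895 and 0.018, and -0.216 and 0.373 without the 2 libraries farthest from the median). Random placement of genes is not excluded: 616 of 10000 shuffles of gene positions gave a window of 20 Mb with as many.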
